A study of Mus musculus with 6 samples.

How the data were processed

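RNA was extracted from sorted cells with a micro-scale column kit and made into stranded mRNA libraries, per the labels' protocols. The submitters' processing notes name fastp, HISAT2 and StringTie and the mouse build GRCm38 (mm10); versions, settings and the gene annotation are not given in the sources used here. The authors deposited 1 table per library with a symbol and a value for each gene. The headers do not state a unit, and the values were read as FPKM (fragments per kilobase of transcript, scaled to sequencing depth) made by the authors: they are not whole numbers, library sums lie between 332289 and 383600, and the smallest steps depend on gene length. FPKM is relative to each library's total, so a rise of abundant transcripts lowers the values of all others. Neither the sort gates nor the time after irradiation is given in the sources used here.

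The files held 30803 rows. Of rows that shared a symbol the row with the highest mean was kept, which dropped 70 rows. All 6 libraries were grouped from their labels and compared in 1 contrast, MHCII-hi minus MHCII-lo. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 12110 in all. The test was limma (version 3.58.1 in R 4.3.3) on log2(FPKM + 1) with an intensity trend in the moderated variance, with no covariate, two-sided, with Benjamini-Hochberg adjustment over all tested genes at 0.05. Fold changes on the log2(FPKM + 1) scale understate the change of low genes, and plain ratios of mean FPKM are given as folds. Adjusted p-values of genes come from this limma fit and those of lists from camera (limma, preset inter-gene correlation 0.01, Benjamini-Hochberg over the 39 lists with at least 5 tested genes). Of the 39 lists, 31 passed with the preset correlation, 21 up and 10 down. With an estimated correlation 14 held: class II presentation, lymphoid priming, type I interferon, interferon gamma, NF-kB, immediate early, oxidative phosphorylation, antioxidant, B cell, plasma cell, T and NK cell, neutrophil, basophil with mast cell and eosinophil, and ribosomal protein genes. Counts adjusted over the list alone use the same p-values with the adjustment restricted to the list's tested genes. The class II check used an exact permutation test of the mean log2 value of 4 genes.

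Before the data were examined, the groups, tests, gene lists, alternatives and the rule for named genes were fixed. The rule named (a) H2-Aa, H2-Ab1, H2-Eb1 and Cd74, (b) the 8 genes with the largest change in each direction among genes past the test whose groups did not overlap, leaving out numbered predicted genes, Rik clones and pseudogenes, and (c) up to 3 members with the smallest p of each list described. Some genes that the rule names are not reported here. Other genes named were chosen after their values were seen: S100a8, S100a9, Ngp, Mzb1, Kit, Ciita, Mecom, Fgd5, Procr, Slamf1 and genes named only in the closing section.

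Depth was not stated. In single-exon genes with 1 transcript and an exon length of 100 to 1000 bases, the lowest values were read as steps of 1 fragment. The position of the first step gave the estimated depth of 2.06e+07 to 3.25e+07 fragments. That step was sought only within a fixed window of values, so a step outside the window would have been missed. The comparison with counting noise rests on this depth. Over genes with at least 200 estimated fragments in a pair, the median squared difference between replicates was 2.51 to 3.23 times counting noise, which does not tell separate animals from repeat preparations of 1 RNA. The libraries were counted separately because the labels number them so. Coordinates and exon lengths come from the GENCODE M21 annotation of GRCm38, in which 98.1% of tested symbols were found; Cstdc4 and Cstdc5 were not among them and carry no coordinates here.

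The gene test and the list test were tested on simulated data with the means of the MHCII-lo libraries and the observed spread. In a run of 12110 genes for this comparison, with 50 genes changed at each size, 42% of genes changed 1.25-fold were called, 68% of those changed 1.5-fold, 86% of those changed 2-fold and 96% of those changed 4-fold, with 7 false calls. A planted list of 25 genes changed 1.5-fold was called, and 0 of 30 unchanged lists were. Every simulated gene was drawn independently, and far fewer genes were changed than the 7093 called in the data. The run therefore does not show how often the list test makes false calls when the genes of a list vary together. Alternatives tried were a replicate block, each library left out in turn, a pseudocount of 0.1, no expression minimum and a minimum of 5 FPKM, quantile and upper-quartile scaling, limma without trend and with robust moderation, a fold threshold, other list tests, and lists without class II members. Alternatives chosen after seeing the data were leaving out immunoglobulin genes, scaling to the summed FPKM without them, and removing a lowess trend over exon length. Tests made for read counts were planned only for count tables and were not run on FPKM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.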

Results

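Gene expression was measured by RNA sequencing in cells labelled as haematopoietic stem cells (HSCs, the bone marrow cells that renew all blood lineages), sorted from wild-type mice that had received 5 Gy of total body irradiation. The cells were divided by their surface level of MHC class II (MHCII), the molecule that presents peptides to CD4 T cells. There were 3 libraries of MHCII-hi cells and 3 of MHCII-lo cells. Each library listed 30733 gene symbols, and between 7653 and 10147 of them were listed at 0. The files gave no read totals. A depth estimated from the smallest steps in the values was 2.25e+07, 2.44e+07 and 2.44e+07 fragments in the MHCII-lo libraries and 3.25e+07, 2.06e+07 and 2.32e+07 fragments in the MHCII-hi libraries. The labels did not say whether replicates came from separate mice, so every p-value below measures only the spread between these libraries, which may be technical. That spread was small: among genes with at least 100 FPKM the median coefficient of variation was 1.97% in MHCII-hi and 1.73% in MHCII-lo. Values below are mean FPKM ± SD with n = 3 libraries per group. Log2 changes are MHCII-hi minus MHCII-lo on the log2(FPKM + 1) scale, and coordinates are those of GRCm38.

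The first question was whether the transcripts of the sorted molecule followed the sort. All 4 class II genes fixed for this check were far higher in MHCII-hi cells. The antigen-presenting chain H2-Aa (chromosome 17, 34282744 to 34287823) stood at 63.7 ± 1.80 against 2.19 ± 0.311 FPKM, a 29.0-fold difference. H2-Ab1 (chromosome 17, 34257689 to 34269419) stood at 81.1 ± 1.89 against 4.71 ± 0.17 FPKM. H2-Eb1 (chromosome 17, 34305867 to 34316674) stood at 69.6 ± 0.974 against 1.67 ± 0.289 FPKM. Cd74, the invariant chain that escorts class II molecules (chromosome 18, 60803848 to 60812652), stood at 359 ± 6.82 against 12.8 ± 0.405 FPKM, a 28.1-fold difference. The mean log2 value of the 4 genes was 6.75 ± 0.02 in MHCII-hi and 2.34 ± 0.05 in MHCII-lo (SD, n = 3). The difference of 4.41 had a two-sided exact permutation p = 0.1, the smallest that 3 libraries against 3 can give. Ciita, the master regulator of class II transcription, was below the expression minimum and was looked up after its values were seen, at 1.84 ± 0.205 against 0.0833 ± 0.0153 FPKM. The 3 libraries of each group lay close together for these genes, and the groups did not overlap.

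**Figure D1:**
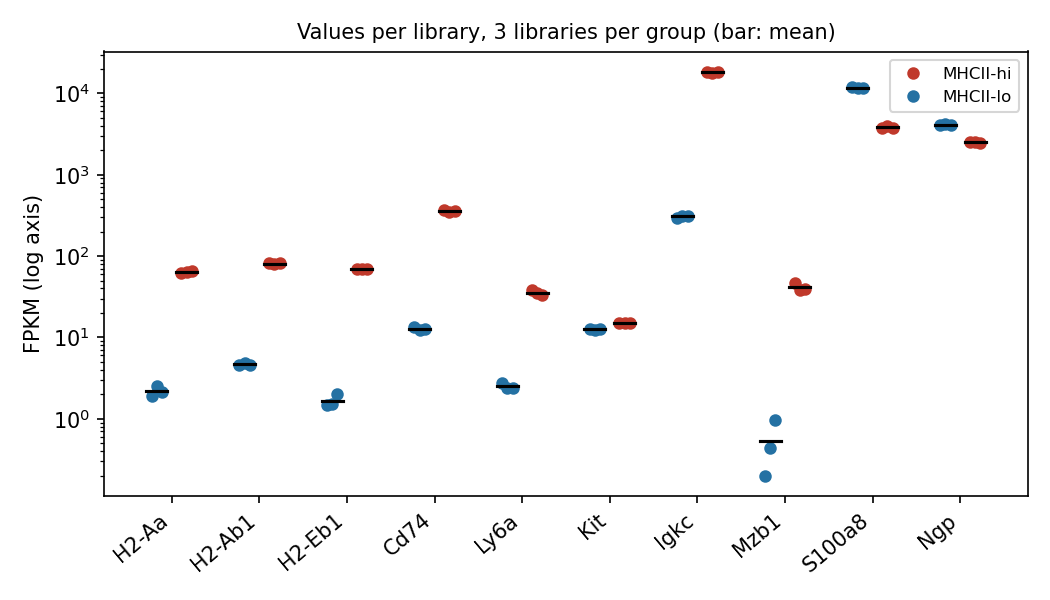
Expression of 10 genes in each library, as FPKM on a log axis, with MHCII-hi libraries in red, MHCII-lo libraries in blue and the mean of 3 libraries as a black bar. The 3 MHCII-hi values of Cd74 lie around a mean of 359 FPKM and the 3 MHCII-lo values around 12.8 FPKM. S100a8 lies lower in MHCII-hi, at 3832 against 11686 FPKM. The genes Ly6a, Kit, Igkc, Mzb1, S100a8 and Ngp were picked for the plot after their values were seen.

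Over all genes, MHCII-hi and MHCII-lo cells differed widely. Of 12110 genes tested, 3084 were higher and 4009 were lower in MHCII-hi cells at a Benjamini-Hochberg adjusted p of 0.05 in limma, 7093 in all. Most changes were small, with a median absolute log2 change of 0.35 among the called genes. A log2 change of at least 1 was reached by 496 higher genes, 221 of them immunoglobulin genes, and by 133 lower genes. The values of the groups did not overlap for 65.8% of the tested genes, against 10% by chance. The first principal component held 91.9% of the variance and separated the groups, and the second held 2.36%. The direction of small changes depended on scaling. Scaling each library to its summed FPKM without immunoglobulin genes moved the median change of all genes by 0.15 and gave 4958 higher and 2079 lower genes. Under it 70.5% of the called genes were higher, in place of 43.5%. Small changes below should be read against that shift. The shift may overstate the effect of immunoglobulin RNA on the scale, because short segments weigh heavily in summed FPKM. Immunoglobulin genes took 23.9% of summed FPKM in MHCII-hi, but 5.93% of FPKM times exon length.

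The largest increases were all in immunoglobulin segments, the pieces that B-lineage cells join to make antibodies. Igkv14-100 (chromosome 6, 68519012 to 68519477) stood at 231 ± 7.42 against 0.803 ± 0.232 FPKM, a log2 change of 7.02 (SE 0.09, limma adjusted p = 7.20e-09). Ighv5-17 stood at 648 ± 10.7 against 4.16 ± 0.924 FPKM, Igkv4-68 at 433 ± 6.79 against 2.60 ± 0.17 FPKM, and Igkv3-12 at 488 ± 16.0 against 3.37 ± 0.869 FPKM. Ighj2, Igkv5-43 and Ighv8-12 had log2 changes of 6.75, 6.72 and 6.70. Igkv5-45 stood at 196.8, 191 and 191 FPKM in the MHCII-hi libraries and was listed at 0, 1.64 and 0 FPKM in the MHCII-lo libraries. Segments of these families share sequence, so the level of any single segment is uncertain. Of 227 immunoglobulin genes tested, 223 rose and 1 fell, and of 199 variable segments 197 rose.

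The largest decreases were in the stefin cluster, a group of near-identical cysteine protease inhibitor genes used by myeloid cells. Stfa2 (chromosome 16, 36403992 to 36408457) stood at 4.20 ± 0.687 against 133 ± 5.82 FPKM, a 31.6-fold lower value in MHCII-hi (log2 change -4.69, SE 0.09, limma adjusted p = 7.06e-08). Stfa3 (chromosome 16, 36450537 to 36455392) stood at 3.41 ± 0.236 against 103 ± 3.34 FPKM, and Stfa1 (chromosome 16, 36276951 to 36285373) at 3.10 ± 0.520 against 71.4 ± 3.87 FPKM. Cstdc5, Cstdc4 and Stfa2l1 had log2 changes of -4.86, -3.61 and -2.85, and how reads were split among these copies is uncertain. Outside the cluster, the skin and neutrophil protease gene Asprv1 fell from 106 ± 1.92 to 8.16 ± 0.993 FPKM and the myeloid gene Wfdc17 from 202 ± 8.07 to 27.7 ± 1.22 FPKM, both written in the direction MHCII-lo to MHCII-hi.

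Markers of B-lineage cells were higher in MHCII-hi cells. All 11 plasma cell genes and all 12 B cell genes tested rose (11 and 12 when adjusted over the list alone). Another 12 of the 24 B cell members lay below the minimum of 1 FPKM. A gene near 0 in MHCII-lo passes that minimum only if it is higher in MHCII-hi, which favours a rise. Median log2 changes of the plasma cell and B cell genes tested were 3.73 and 2.11, with camera adjusted p of 3.46e-10 and 4.73e-09. The kappa constant region Igkc rose from 309 ± 9.98 to 18162 ± 280 FPKM between MHCII-lo and MHCII-hi. The heavy chain constant region of IgA, Igha, stood at 2306 ± 42.5 against 21.8 ± 1.87 FPKM. Ighg2c stood at 2842 ± 24.1 against 72.1 ± 1.67 FPKM, and Ighg2b at 1816 ± 16.2 against 28.9 ± 1.63 FPKM. The B cell receptor component Cd79a stood at 24.3 ± 0.690 against 0.280 ± 0.145 FPKM, and the B-lineage coactivator Pou2af1 at 15.5 ± 1.0 against 0.297 ± 0.0651 FPKM. Immunoglobulin genes took 23.9% ± 0.141 of the summed FPKM of MHCII-hi libraries and 0.501% ± 0.00477 of MHCII-lo libraries (SD, n = 3). Their share of FPKM times exon length, which weighs short segments less, was 5.93% ± 0.0206 and 0.110% ± 0.00175 (SD, n = 3). In the T and NK cell list, 23 of 24 genes rose and 1 did not pass (23 adjusted over the list alone; median log2 change 1.29, camera adjusted p = 3.14e-11). Among them were the interleukin-2 receptor chain Il2rb, at 15.9 ± 0.936 against 3.04 ± 0.122 FPKM, the costimulatory receptor Cd28 and the T cell receptor constant region Trbc2.

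Neutrophil genes moved the other way. All 21 tested genes of the neutrophil list fell (21 adjusted over the list alone), with a median log2 change of -1.36 and a camera adjusted p of 2.97e-14. The collagenase Mmp8 stood at 144 ± 0.961 against 595 ± 6.90 FPKM, the chitinase-like protein Chil3 at 730 ± 8.85 against 2386 ± 32.8 FPKM, and the iron-binding protein Lcn2 at 217 ± 0.930 against 593 ± 0.371 FPKM. S100a8 and S100a9, which form the neutrophil protein calprotectin, together took 2.72% ± 0.0526 of the summed FPKM in MHCII-hi and 8.58% ± 0.110 in MHCII-lo (SD, n = 3). In the list of neutrophil and monocyte progenitors, 18 genes fell, 3 rose and 1 did not pass (21 adjusted over the list alone), and 15 fell and 5 rose when libraries were scaled without immunoglobulin genes. The genes that fell included the granule protease Ctsg, at 666 ± 11.2 against 1446 ± 32.2 FPKM, with Ms4a3 and F13a1. Its camera adjusted p was 2.37e-05, and the adjusted p was 0.0992 with an estimated correlation.

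**Figure D2:**
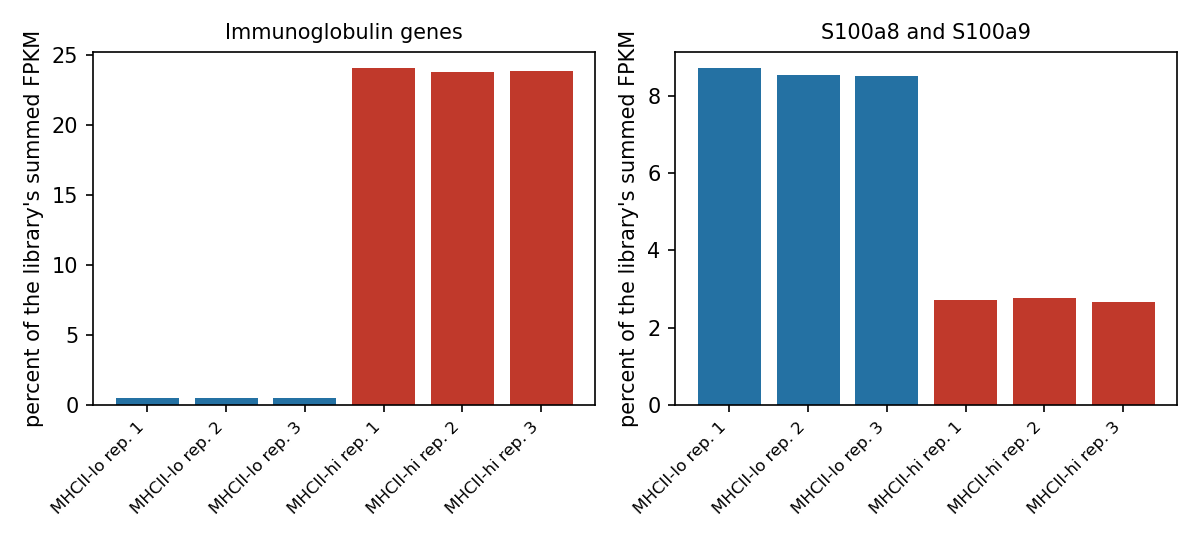
Share of each library's summed FPKM taken by immunoglobulin genes (left) and by S100a8 with S100a9 (right), in percent, as 1 bar per library. Immunoglobulin genes take 23.8% to 24.0% in the 3 MHCII-hi libraries and 0.497% to 0.506% in the 3 MHCII-lo libraries, and S100a8 with S100a9 take less in MHCII-hi. Weighted by exon length, which is not drawn, immunoglobulin genes take a mean of 5.93% in MHCII-hi and 0.110% in MHCII-lo.

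Markers of other marrow cell types also differed. In the basophil, mast cell and eosinophil list 17 genes rose, 1 fell and 1 did not pass (18 adjusted over the list alone; median log2 change 0.98, camera adjusted p = 9.67e-10). The eosinophil granule protein gene Prg2 stood at 4902 ± 75.2 against 2024 ± 15.4 FPKM. The eosinophil ribonuclease genes Ear6 and Ear1, which share reads with close relatives, stood at 516 ± 4.56 against 109 ± 2.98 FPKM and 935 ± 26.4 against 272 ± 3.71 FPKM. The conventional dendritic cell list had 10 genes that rose, 4 that fell and 3 that did not pass (15 adjusted over the list alone). It had a camera adjusted p = 0.00510, but adjusted p = 0.0726 with an estimated correlation and 0.0571 with a minimum of 5 FPKM. It was led by the lectin Cd209a at 16.4 ± 0.523 against 0.60 ± 0.139 FPKM, the transcription factor Irf4 and the lectin Clec10a. Irf4 is also in the plasma cell list, whose median log2 change was 3.73. For plasmacytoid dendritic cells 9 rose, 1 fell and 1 did not pass (10 adjusted over the list alone). Their camera adjusted p was 6.00e-04, and adjusted p = 0.0568 with an estimated correlation. Ly6d and Dntt were higher. The monocyte and macrophage list had 7 that rose, 11 that fell and 2 that did not pass (18 adjusted over the list alone) with a camera adjusted p of 0.177, which became 0.0287 without MHCII-hi replicate 1 and 0.0416 when scaled without immunoglobulin genes. The lysozyme Lyz2 fell to 1762 ± 28.9 from 2652 ± 15.4 FPKM, as did Cd14 and Ctsd. Erythroblast genes fell in 12 cases, rose in 1 and did not pass in 5 (14 adjusted over the list alone), but 6 fell and 5 rose when libraries were scaled without immunoglobulin genes. The list had a camera adjusted p = 0.0260, an adjusted p = 0.0992 with an estimated correlation and 0.0505 with a minimum of 5 FPKM. The globins Hbb-bs, Hbb-bt and Hba-a2, which share reads, were among those that fell. Of the 5 endothelial and 5 stromal genes tested, 4 rose in each and 1 did not pass in each (4 and 5 adjusted over the list alone). Below the minimum of 1 FPKM lay 18 of 23 endothelial and 17 of 22 stromal members. The camera adjusted p values were 0.0337 and 0.0204, but adjusted p = 0.119 and 0.0992 with an estimated correlation. When scaled without immunoglobulin genes they became 0.0918 and 0.0752. Pecam1, Eng and Tie1 were the endothelial genes with the smallest p, and Runx2, Cxcl12 and Vcam1 the stromal ones.

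Genes known for HSC identity and for lineage choice differed in both directions. In the long-term HSC list 16 genes rose, 5 fell and 4 did not pass (21 adjusted over the list alone), and 22 of 47 members lay below the minimum of 1 FPKM. Its camera adjusted p was 4.55e-04, and the adjusted p was 0.0568 with an estimated correlation. Among the members that rose were the stem cell antigen Ly6a, at 35.5 ± 2.74 against 2.50 ± 0.193 FPKM, and the transcription factor Egr1, at 100.2 ± 2.73 against 31.1 ± 1.27 FPKM. Egr1 is also in the immediate early list, which was fixed as a technical list. The interferon-induced gene Ifitm1 fell to 35.4 ± 2.0 from 94.5 ± 2.94 FPKM. Mecom, Fgd5, Procr and Slamf1, genes widely used to mark HSCs, were looked up after their values were seen and reached at most 0.497 FPKM in either group. Against what the label would lead to expect, the neutrophil gene S100a9 stood at 6575 ± 127 against 16860 ± 163 FPKM. The receptor Kit stood at 15.0 ± 0.10 against 12.6 ± 0.0751 FPKM. In the lymphoid priming list 18 rose, 1 fell and 1 did not pass (19 adjusted over the list alone; median log2 change 1.27, camera adjusted p = 4.73e-09). Its leading genes Jchain and Ighm are antibody genes, and Cd79a is a B cell receptor gene. Megakaryocyte and platelet genes rose in 21 cases, fell in 5 and did not pass in 4 (28 adjusted over the list alone), with camera adjusted p = 1.77e-04 and adjusted p = 0.0992 with an estimated correlation. Thbs1, a platelet adhesion protein gene, stood at 129 ± 0.909 against 56.5 ± 0.284 FPKM, and Tubb1 and Itga2b were higher too. The multipotent progenitor list was even, with 9 that rose, 9 that fell and 3 that did not pass (19 adjusted over the list alone, camera adjusted p = 0.985). Its median log2 change was 0.03, its mean was -0.01 and its test direction was down, and 12 rose and 7 fell when libraries were scaled without immunoglobulin genes. Wfdc17, Ighm and Plac8 led it. Erythroid progenitor genes rose in 9 cases, fell in 2 and did not pass in 9 (11 adjusted over the list alone, camera adjusted p = 0.0521), but 4 rose and 4 fell under quantile normalization. The list passed without MHCII-hi replicate 2 (0.0380), on ranks (0.0408), with upper-quartile scaling (0.04998), without immunoglobulin genes (0.0304) and with the exon length trend removed (0.0208). Tfrc was lower, and Aqp1 and Zfpm1 were higher. Of the adhesion and niche receptors 13 rose, 5 fell and 5 did not pass (19 adjusted over the list alone), with camera adjusted p = 0.0107 and adjusted p = 0.0831 with an estimated correlation. The receptor Acvrl1 was lower, and the integrin Itga4 and the sphingosine receptor S1pr1 were higher. Plasma cell markers, at a median log2 change of 3.73, and neutrophil markers, at -1.36, moved beside all of these lists.

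Antigen presentation and immune signalling genes were mostly higher in MHCII-hi cells. In the class II list 12 genes rose, 1 fell and 2 did not pass (13 adjusted over the list alone; median log2 change 1.02, camera adjusted p = 4.37e-06). This list contains the sorted molecule, so its direction was set by the sort. In the class I list 13 rose, 5 fell and 3 did not pass (18 adjusted over the list alone), with camera adjusted p = 0.00378 and adjusted p = 0.194 with an estimated correlation. H2-Q7, H2-Q6 and H2-Q4, which share reads with other H2-Q genes, had the smallest p and rose. H2-Q6 stood at 63.7 ± 1.23 against 18.5 ± 1.22 FPKM. The costimulation and checkpoint ligand list had 8 that rose, 2 that fell and 3 that did not pass (10 adjusted over the list alone; camera adjusted p = 0.0507). It passed without MHCII-lo replicate 1 (0.0483), without MHCII-hi replicate 1 (0.0351), with no expression minimum (0.0170), with upper-quartile scaling (0.04998), without immunoglobulin genes (0.0304) and with the exon length trend removed (0.0244). Btla and the checkpoint ligand Cd274 were higher and Cd47 was lower. For the type I interferon response 29 rose, 8 fell and 7 did not pass (39 adjusted over the list alone; median log2 change 0.32, camera adjusted p = 1.17e-04). Ifi203 and Epsti1 were higher and Slfn1 was lower. For interferon gamma 17 rose, 4 fell and 7 did not pass (21 adjusted over the list alone; camera adjusted p = 1.29e-04). Ly6a led it, with the transcription factor Irf1 at 24.3 ± 0.618 against 10.9 ± 0.686 FPKM and with Nlrc5, a regulator of class I genes. NF-kB genes rose in 23 cases, fell in 6 and did not pass in 2 (29 adjusted over the list alone; camera adjusted p = 7.85e-06). The feedback inhibitor Tnfaip3 stood at 91.2 ± 1.13 against 29.8 ± 0.283 FPKM, while Lcn2 and the cytokine Il1b, both abundant in neutrophils, fell. Immediate early genes, which cells switch on within minutes of a stimulus, rose in 22 cases, fell in 2 and did not pass in 3 (24 adjusted over the list alone; median log2 change 0.68, camera adjusted p = 9.67e-10). Fosb stood at 185 ± 4.80 against 70.7 ± 1.26 FPKM and Jun at 498 ± 3.90 against 269 ± 4.41 FPKM. The immediate early list had been fixed as a technical list, not as one of biology. Whether handling or sorting of the cells shaped it was not tested. B-lineage and T cell markers rose alongside these lists, with median log2 changes of 2.11 and 1.29.

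As deposited and with the preset correlation, the DNA replication list was slightly lower, and the list of cell cycle inhibitors slightly higher, in MHCII-hi cells. In the DNA replication list 31 genes fell, 2 rose and 21 did not pass (33 adjusted over the list alone), but 20 fell and 12 rose when libraries were scaled without immunoglobulin genes, with a median log2 change of -0.0049 and camera adjusted p = 0.0154. Under quantile normalization 31 fell and 3 rose, and under upper-quartile scaling 29 fell and 4 rose. As deposited the median was -0.16, with camera adjusted p = 2.21e-04 and adjusted p = 0.0568 with an estimated correlation. Ccne2, a cyclin of S phase entry, stood at 8.78 ± 0.266 against 15.4 ± 0.145 FPKM, and Cdca7 and Rfc4 were lower. For mitosis 32 fell, 14 rose and 18 did not pass (48 adjusted over the list alone, camera adjusted p = 0.124), but 30 rose and 11 fell when libraries were scaled without immunoglobulin genes. Its adjusted p was 0.00104 with no expression minimum. Pbk, Ccna2 and Ccnb1 had the smallest p and fell. Cell cycle inhibitors and quiescence genes rose in 16 cases, fell in 6 and did not pass in 3 (23 adjusted over the list alone), with camera adjusted p = 0.00192 and adjusted p = 0.119 with an estimated correlation. They were led by Egr1 and the nuclear receptors Nr4a2 and Nr4a1, which are also immediate early genes. Among targets of p53, the regulator of the DNA damage response, 20 rose, 11 fell and 10 did not pass (31 adjusted over the list alone), and 24 rose and 4 fell when libraries were scaled without immunoglobulin genes. This list had a camera adjusted p = 0.0426 and adjusted p = 0.0992 with an estimated correlation. Pmaip1, a cell death activator, stood at 27.3 ± 0.335 against 15.6 ± 0.798 FPKM, while Sesn1 was higher and Rps27l lower. The camera adjusted p of this list became 0.0556 without MHCII-lo replicate 3, 0.0737 with no expression minimum and 0.125 when scaled without immunoglobulin genes. DNA double-strand break repair genes mostly did not pass, at 33 of 45, with 2 that rose and 10 that fell (8 adjusted over the list alone, camera adjusted p = 0.877), but 21 rose and 3 fell when libraries were scaled without immunoglobulin genes. Xrcc5 was among the genes that fell. The apoptosis list had 11 that rose, 11 that fell and 9 that did not pass (23 adjusted over the list alone, camera adjusted p = 0.672). It had a median log2 change of -0.07, a mean of 0.09 and the test direction up, and 13 rose and 6 fell when libraries were scaled without immunoglobulin genes. Bcl2, a survival gene, was higher and Cycs lower. In the senescence and fibrosis-related secretion list 5 rose, 6 fell and 1 did not pass (11 adjusted over the list alone, camera adjusted p = 0.912), but 6 rose and 3 fell when libraries were scaled without immunoglobulin genes. Il1b and Ccl2 were lower and Cxcl2 was higher. These lists stood beside the fall of the neutrophil markers, at a median log2 change of -1.36.

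As deposited and with the preset correlation, most metabolic gene lists were lower in MHCII-hi cells. Of 75 nuclear-encoded oxidative phosphorylation genes 68 fell, 0 rose and 7 did not pass (70 adjusted over the list alone; median log2 change -0.38, camera adjusted p = 2.54e-13). Cox7a2, a respiratory chain subunit gene, stood at 50.6 ± 1.95 against 91.8 ± 1.78 FPKM, with Cycs and Cox7b also lower. Their median was -0.26 with the trend over exon length removed and -0.20 when libraries were scaled without immunoglobulin genes, where 50 fell and 1 rose. Of the 13 transcripts encoded by the mitochondrion 10 rose, 1 fell and 2 did not pass (11 adjusted over the list alone), but 4 rose and 7 fell under quantile normalization. Their median log2 change was 0.21, with camera adjusted p = 1.29e-04 and adjusted p = 0.194 with an estimated correlation. mt-Atp8, mt-Cytb and mt-Atp6 led that list, and these genes share reads with nuclear copies. Glycolysis genes fell in 14 cases, rose in 2 and did not pass in 5 (16 adjusted over the list alone), and 12 fell and 5 rose when libraries were scaled without immunoglobulin genes. This list had a camera adjusted p = 6.64e-04 and adjusted p = 0.217 with an estimated correlation. Lactate dehydrogenase Ldha stood at 123 ± 2.30 against 214 ± 5.45 FPKM, and Tpi1 and Pkm were lower. Antioxidant genes fell in 18 cases, rose in 4 and did not pass in 5 (22 adjusted over the list alone; camera adjusted p = 6.00e-04), and 14 fell and 7 rose when libraries were scaled without immunoglobulin genes. Among them G6pdx, which supplies NADPH, stood at 80.2 ± 0.718 against 151 ± 1.85 FPKM, with Mgst1 and Prdx1. Cholesterol synthesis genes fell in 13 cases, rose in 2 and did not pass in 7 (15 adjusted over the list alone), but 6 fell and 3 rose when libraries were scaled without immunoglobulin genes. They had a camera adjusted p = 0.0289, adjusted p = 0.0992 with an estimated correlation and 0.360 with a minimum of 5 FPKM. Msmo1 was lower and Insig1 was higher. Heat shock and protein folding genes fell in 19 cases, rose in 9 and did not pass in 4 (28 adjusted over the list alone), but 15 fell and 11 rose when libraries were scaled without immunoglobulin genes. Their list had a camera adjusted p = 0.0248, adjusted p = 0.0992 with an estimated correlation and 0.175 with a minimum of 5 FPKM. The chaperones Hsp90aa1 and Hspa8 were lower, and Herpud1, a reticulum stress gene, was higher, at 72.7 ± 1.67 against 29.3 ± 0.785 FPKM. Ribosomal protein genes fell in 58 cases, rose in 4 and did not pass in 19 (65 adjusted over the list alone; median log2 change -0.16, camera adjusted p = 1.69e-08), but 25 rose and 22 fell when libraries were scaled without immunoglobulin genes. The adjusted p was then 0.0509, and 0.0569 with the exon length trend removed. Rps25, Rps27l and Rps7 led the list. Neutrophil genes fell alongside all of these lists.

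**Figure D3:**
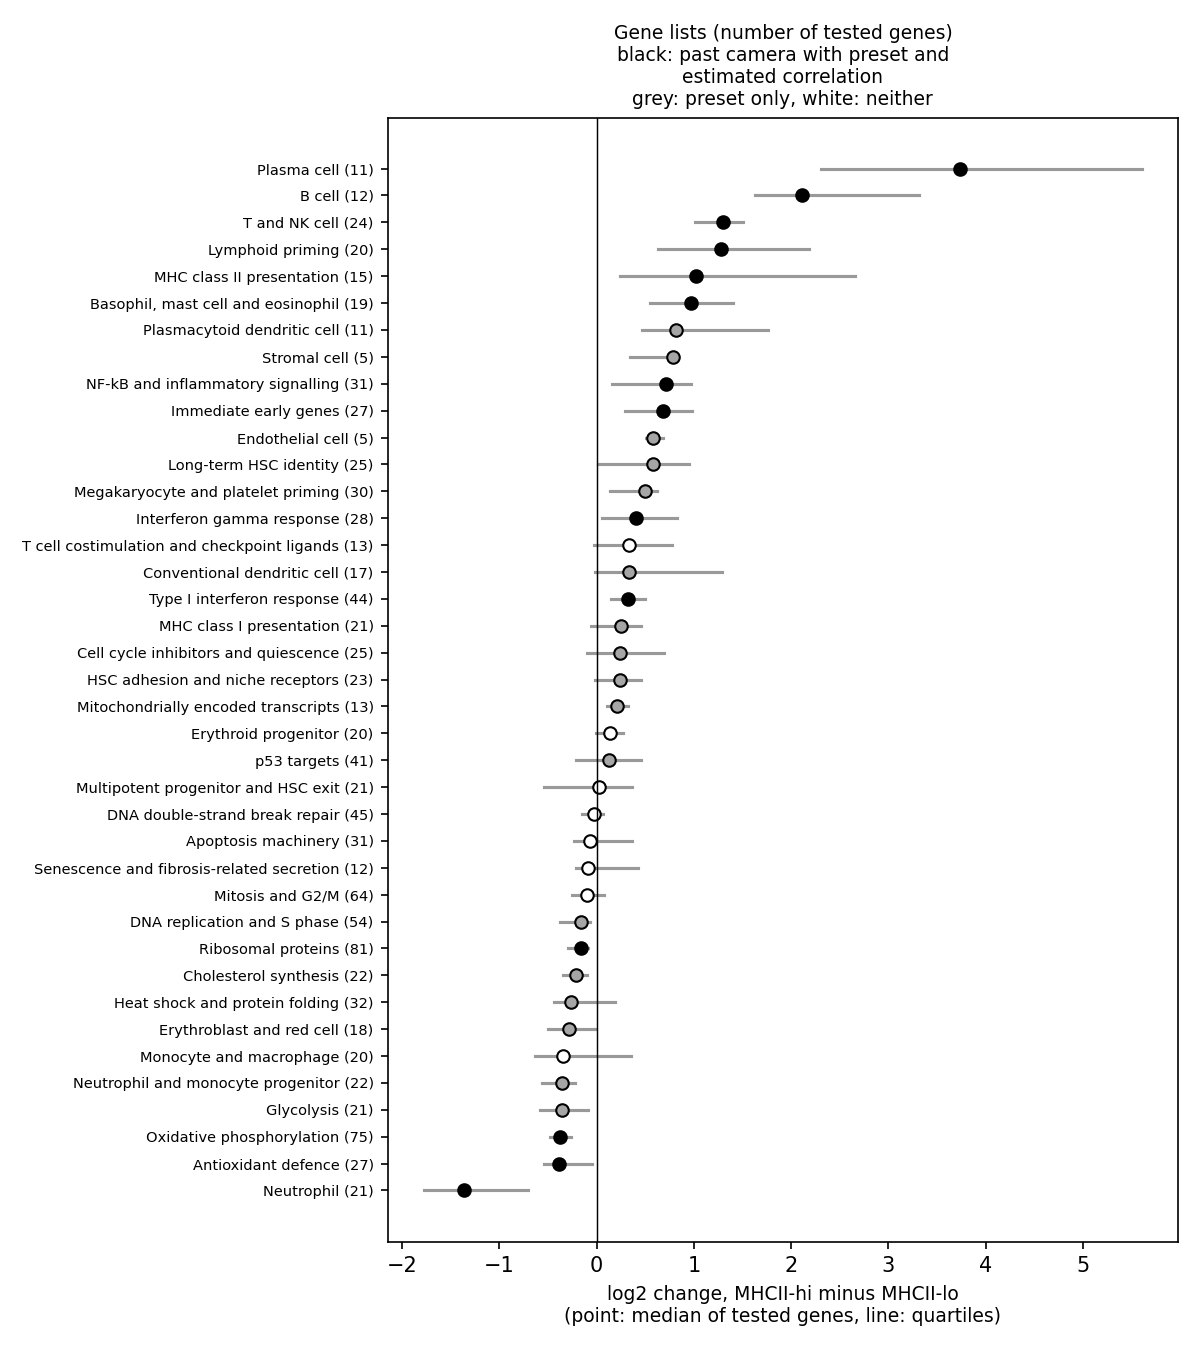
Median log2 change, MHCII-hi minus MHCII-lo, of the tested genes in each of 39 lists (points) with the quartiles of the genes (lines), and the number of tested genes in brackets. The plasma cell list has the highest median, 3.73, and the neutrophil list the lowest, -1.36; black points passed the camera test with both a preset and an estimated correlation, grey points with the preset only, and white points with neither.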

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

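The count of genes past the limma threshold (7093 in the reported fit) lay between 6364 and 6542 when each library was left out in turn, with 2716 to 2922 higher and 3583 to 3693 lower. It fell to 629 (496 higher, 133 lower) with an added log2 change of at least 1, where fewer genes can pass by construction. A minimum of 5 FPKM left 1792 higher genes, since fewer genes were tested. Scaling without immunoglobulin genes, chosen after seeing the data, gave 4958 higher and 2079 lower genes; the shift of the median by 0.15 accounts for the turn in the split. No gene named by the fixed rule changed direction or its side of the threshold under the alternatives that gave it a value; genes chosen after their values were seen were not run under them, except the markers in the closing section, under 1 scaling. The class II check kept its direction under every alternative run. The count of lists fell from 31 to 14 with an estimated correlation and stayed within 1.5 times of 31 elsewhere. The cholesterol, p53 and heat shock lists lost their call with estimates of -0.0317, -0.0217 and -0.00678, below the preset 0.01. Their unadjusted camera p rose from 0.0215, 0.0339 and 0.0171 to 0.0647, 0.0661 and 0.0526. For these lists a correlation above the preset is argued against as the cause. That holds too for the adhesion and niche receptor list (estimate -0.0251) and the conventional dendritic cell list (-0.0104). It also holds for the erythroblast (-0.0152), endothelial (-0.0381) and stromal (-0.157) lists. The rest of the lists that lost their call had estimates above the preset, such as glycolysis at 0.256. With an estimate, camera also judges its statistic on the 4 residual degrees of freedom of the fit, far fewer than with the preset. This by itself raises p-values. Oxidative phosphorylation, with an estimate of 0.0055, also below the preset, went from an unadjusted camera p of 1.30e-14 to 0.00102. How much of each loss the degrees of freedom account for was not tested. The mitochondrially encoded list reversed under quantile normalization (median -0.12, camera adjusted p = 0.484), and the cause was not tested. Over all other pairs of a list and an alternative, 28 lost a call and 24 gained one, so a list can count more than once. The estimated correlation gave 17 of the losses, and fry, another list test, gave 8 of the gains. The first component held 87.3% with a pseudocount of 0.1, 85.8% without a minimum, 96.0% with a minimum of 5 FPKM, 91.5% under quantile normalization, 92.3% scaled without immunoglobulin genes, 92.2% with the length trend removed, 78.2% without immunoglobulin genes and 95.4% on the 1000 most variable genes. The replicate block gave 6638 genes, and the costimulation and erythroid progenitor lists passed under it (camera adjusted p = 0.0445 for both). No pairing by replicate number was detected. Same-numbered residuals correlated at -0.09, -0.0036 and -0.03, and no MHCII-hi library correlated best with the MHCII-lo library of its number. With 3 libraries per group and a spread that may be technical, these values cannot exclude a shared source of same-numbered libraries. Leaving out each library gave a first component of 92.0% to 92.7%. The median coefficient of variation in MHCII-hi was 7.52% at 1 to 10 FPKM and 1.97% at 100 FPKM or more, so small differences are hardest to detect in low genes; how far depth sets this was not tested.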

Other observations

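Antibody classes differed in how far they rose, as looked up after the values were seen. The heavy chains Igha, Ighg1, Ighg2b and Ighg2c were 105.6-fold, 84.5-fold, 62.8-fold and 39.4-fold higher in MHCII-hi, with Ighg1 at 1617 ± 11.4 against 19.1 ± 1.32 FPKM (SD, n = 3). Ighg3, also class-switched, was 6.13-fold higher, and the unswitched Ighm and Ighd were 4.30-fold and 10.5-fold higher, Ighd at only 1.79 ± 0.262 FPKM in MHCII-hi. Ighe was listed at 0 in the MHCII-lo libraries. The joining chain Jchain stood at 1342 ± 12.95 against 14.2 ± 1.45 FPKM, and the mature B cell genes Ms4a1 and Pax5 at 1.36 ± 0.210 and 1.21 ± 0.326 FPKM in MHCII-hi. Ctla4, an inhibitory T cell receptor, stood at 6.47 ± 0.251 against 0.520 ± 0.0458 FPKM.

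The tests of explanations below were chosen only after the patterns were seen, except the counts of splits. Over the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes past the threshold (7093, highest other 0), the real split. The real split was also the only 1 with as many higher (3084, highest other 0), as many lower (4009, highest other 0) and as many lists (31, highest other 19). These 10 splits are too few for a share under 0.05. Every other split mixes the groups, so the group difference enters its spread and few genes can pass. A highest other of 0 is therefore no measure of chance.

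Immunoglobulin transcripts were higher in MHCII-hi cells. Reads shared between near-identical segments are argued against as the whole cause, since they leave the summed share of immunoglobulin fragments as it is. That share was 54.1 times higher (5.93% ± 0.0206 against 0.110% ± 0.00175, SD, n = 3). The deposited scaling is argued against by the same share, in which a factor common to all genes of a library cancels. Scaling without immunoglobulin genes gave them a median log2 change of 5.46. That value is no test of scaling, because removing these genes from the total raises MHCII-hi values and their change could only grow. Plasma cells or their RNA in the MHCII-hi fraction stay open as a candidate explanation. Of 11 plasma cell markers in none of the fixed lists 7 were higher as deposited, or 63.6%, below the 80% set as needed. When scaled without immunoglobulin genes 9 were higher, or 81.8%, which meets the 80%, so the outcome turns with the scaling. With 9 markers whose lists had already been seen to rise, 16 of 20 were higher, while Fkbp11 fell under both scalings (2.44 ± 0.295 against 3.45 ± 0.204 FPKM) and Ssr4 fell as deposited only (35.3 ± 1.13 against 40.9 ± 1.42 FPKM). Of these 20 markers, 10 stood at 1 FPKM or more in MHCII-lo as well, Fkbp11 and Ssr4 among them. The markers below 1 FPKM in MHCII-lo all rose, which the minimum mean of 1 FPKM favours. A gate against mature blood cells would remove such cells, but the gates are not given in the sources used here, and expression by the stem cells themselves stays open and untested.

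Neutrophil genes were lower in MHCII-hi, while the lists of other cells moved in both directions. The medians of the other cell lists lay 4.07 apart between the highest (plasma cell, 3.73) and the lowest (monocyte and macrophage, -0.34). That distance is part of the pattern itself and shows only that those lists did not move together. A lower share of neutrophil-lineage cells as the whole cause was therefore not tested separately. More neutrophil-lineage cells or their RNA in the MHCII-lo fraction may be part of it: of 24 markers in none of the fixed lists, 22 were lower in MHCII-hi, or 91.7% (21 when scaled without immunoglobulin genes), among them Anxa1 at 226 ± 0.480 against 570.2 ± 4.08 FPKM and Hp at 245 ± 5.60 against 591 ± 12.3 FPKM, while Slpi and Ccl6 were higher. These markers were listed after the data were seen, and 4 of 28 were left out: Lrg1, Olfm4 and Ceacam10 because their fall had already been seen, and Hdc because the fixed basophil list holds it. A difference between the stem cells of the groups stays open and untested. The label rests on the sort, and Mecom, Fgd5, Procr and Slamf1, genes widely used to mark HSCs, reached at most 0.497 FPKM in either group.

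Immunoglobulin variable segments varied little between the 3 MHCII-hi libraries. Over 175 segments with at least 10 FPKM the median coefficient of variation was 3.37%, against 3.47% in genes matched on the product of FPKM and exon length, 20 genes to each segment. Whether the 3 libraries were drawn from 1 pool of cells or RNA cannot be told apart from separate animals by this value, because how far summed segment use differs between animals was not measured, and the labels do not say how the replicates were made.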
